A study of Arabidopsis thaliana with 9 samples.

How the data were processed

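PolyA RNA of Arabidopsis thaliana seedlings of the Col ecotype was sequenced in 9 libraries, 3 biological replicates each of wild type, the hda9-1 mutant and the pwr-2 mutant, called WT, hda9 and pwr here. All seedlings were 10 days old, grown on MS plates in long days, and the libraries were stranded, made with dUTP and pooled in equal amounts, per the labels' protocols. HISAT2 and the TAIR10 genome are named in the submitters' processing notes. The deposited table holds whole-number read counts per gene, 1 column per library, with no normalization. The sources used here do not state the counting tool, its strand setting or its treatment of duplicate and multiply mapped reads. Reads of genes that overlap, or that have near-identical copies, may therefore be assigned to the other gene. Of 112 named genes, 27 share exon bases with another annotated gene, and their values are uncertain to that extent. The shares of at least 10% were CHS1 90.5%, MRD1 83.1%, FLC 68.1%, SOC3 48.3%, BOA 45.9%, HEI10 40.9%, bHLH38 35.7%, XTH15 31.6%, SMZ 30.6%, ARR6 23.9%, NPX1 19.6%, LUX 17.8%, SHP1 17.5%, ADR1-L1 16.6%, UBC21 15.5%, SPL4 14.4%, SRT2 13.5%, LHCB6 11.9% and RVE1 11.2%.

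The table has 29420 gene identifiers, of which 4396 have no count in any library. A RefSeq annotation of assembly TAIR10.1 gave names and positions to 28932 of them, and positions are printed in that assembly. The total count per library was 6450661 to 11150773, so that 3 counts, taken as the floor of detection, correspond to 0.269 to 0.465 CPM, counts scaled to a common library size. Floors and counting intervals cover counting error only, since reads copied by PCR are not independent molecules. Log2 CPM, where used, took a prior count of 2. CPM were computed from each library's total times its TMM factor and are given as mean ± SD of 3 libraries.

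Differences between groups were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filter filterByExpr, which left 20171 genes, and 1 model over all 9 libraries with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene is called changed at an adjusted p under 0.05. Log2 fold changes come from the same fits, and SE is the absolute log2 fold change divided by the square root of F. Adjusted p-values without another tool's name are edgeR's. The steps were tested on simulated counts in which 67, 67 and 66 genes were changed by a log2 fold change of 0.5, 1 and 2. For hda9 against WT, in 20038 genes, 71.6% of the genes changed by a log2 fold change of 0.5 were recovered, 88.1% at 1 and 97.0% at 2, with 13 false calls. For pwr against WT, in 20031 genes, the shares were 65.7%, 83.6% and 92.4%, with 5 false calls. For pwr against hda9, in 20015 genes, they were 67.2%, 91.0% and 95.5%, with 11 false calls. The false calls were 7.07%, 3.01% and 6.11% of all calls in the 3 comparisons. Far fewer genes were changed than are called in the data, and no trend with expression level was imposed. These shares therefore need not hold for the data.

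The 19 gene lists held 362 members, of which 303 were measured: the targeted genes, histone deacetylases and partners, flowering time, floral organ identity, seed maturation, abscisic acid (ABA) with drought and cold response, leaf senescence, salicylic acid defence, NLR immune receptors, jasmonate and wounding, auxin with shade or warmth growth, photosynthesis, circadian clock, glucosinolate synthesis, flavonoid and anthocyanin synthesis, heat shock, root tissue markers, shoot meristem markers and reference genes. Each list was tested against all other genes with camera (limma 3.58.1, voom values, preset correlation of 0.01), again with a correlation estimated from the data, and with fry, which asks whether the members move one way on balance. These p-values were adjusted over the lists within each comparison, leaving out the targeted genes. The lists, tests, comparisons, alternatives and the rule for naming genes were chosen before the data were examined. By that rule the text names HDA9 and PWR, and for each mutant against WT the 10 largest rises and 10 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and all 3 mutant libraries on the same side of all 3 WT libraries. It adds up to 4 called members per list with the smallest adjusted p, FLC, FT, AGL19 and SOC1 whatever their p, and 5 genes each way for pwr against hda9. Genes named outside this rule, among them the members of small counts, were chosen after their values were seen.

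Shared calls of the 2 mutants were set beside the number expected for independent lists and beside 20 simulations of unchanged groups compared with the same simulated WT libraries. Direction was compared over 5 classes of genes of equal size by mean expression, with Fisher's exact test of the lowest class against the others. The share of called genes within 1000 kb of each mutated gene was compared with the rest of the genome by Fisher's exact test, two-sided.

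The replicate numbers are shared by the 3 genotypes in the labels, with no statement of what they mark. Deviations from the group means correlated between same-numbered WT and hda9 libraries at 0.36, 0.45 and 0.46, each above the threshold of 0.1 set for pairing. The numbers may therefore pair these groups, on evidence from the data alone. Deviations within a group cancel out, so these correlations are not independent. The main fit holds no term for the number, and a block for it is among the alternatives.

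Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, the 6 libraries of the compared groups alone, a block for the replicate number, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. Cyclic-loess offsets (span 0.7), alone and with the block, were added after seeing the data. In simulated data of hda9 against WT with an imposed trend, in 19937 genes, they moved the median log2 fold change of the lowest class from -0.22 to -0.01. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. For named genes with a group mean of at most 3 counts, an interval for the log2 ratio of summed counts was taken from an exact binomial interval, which covers counting error only.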

Results

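Transcripts were counted in whole seedlings of Arabidopsis of 3 genotypes: wild type (WT), hda9, which carries a mutation in the histone deacetylase gene HDA9, and pwr, with a mutation in POWERDRESS (PWR), which encodes a protein with SANT domains. The series title states that PWR and HDA9 interact and promote deacetylation of histone H3, so the comparisons ask which transcripts differ from WT in each mutant and whether the mutants differ from each other. Each genotype had 3 biological replicates. The libraries held 10184314, 11150773 and 8260650 counts in WT, 9417469, 9161717 and 6450661 in hda9, and 8261697, 9398515 and 8955101 in pwr. Between 22039 and 23338 genes had at least 1 count, and the most abundant gene took 0.0690% to 0.0901% of a library. Replicate 3 of hda9 stood apart, as the smallest library and with 251 CPM on annotated ribosomal RNA genes, against 35.4 to 102 CPM in the other 8 libraries.

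HDA9 (AT3G44680, chromosome 3, 16226519 to 16230009) had 405, 454 and 309 counts in the WT libraries, 68, 67 and 40 in hda9, and 290, 290 and 272 in pwr. It fell in hda9 from 38.0 ± 1.4 to 7.04 ± 0.44 CPM (SD, n = 3), a log2 fold change of -2.42 (SE 0.09, adjusted p = 3.2e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). PWR (AT3G52250, chromosome 3, 19376138 to 19383369) had 1531, 1668 and 1125 counts in WT, 1786, 1788 and 1146 in hda9, and 353, 532 and 400 in pwr. Its level fell in pwr from 140.7 ± 6.8 to 48.7 ± 7.4 CPM, a log2 fold change of -1.53 (SE 0.09, adjusted p = 1.2e-06). In hda9, PWR rose to 191 ± 5.5 CPM (log2 fold change 0.44, SE 0.08, adjusted p = 0.0015). HDA9 in pwr, at 32.6 ± 2.7 CPM, had a log2 fold change of -0.23 (SE 0.07, adjusted p = 0.033), a call that ended without WT replicate 1 (0.102), WT replicate 2 (0.128), pwr replicate 2 (0.127) or pwr replicate 3 (0.114), with DESeq2 (0.151) and with loess offsets (0.342). Of 2 close relatives of HDA9 near it on the chromosome, HDA10 had 6 counts and HDA17 had 9 counts over all 9 libraries.

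**Figure D1:**
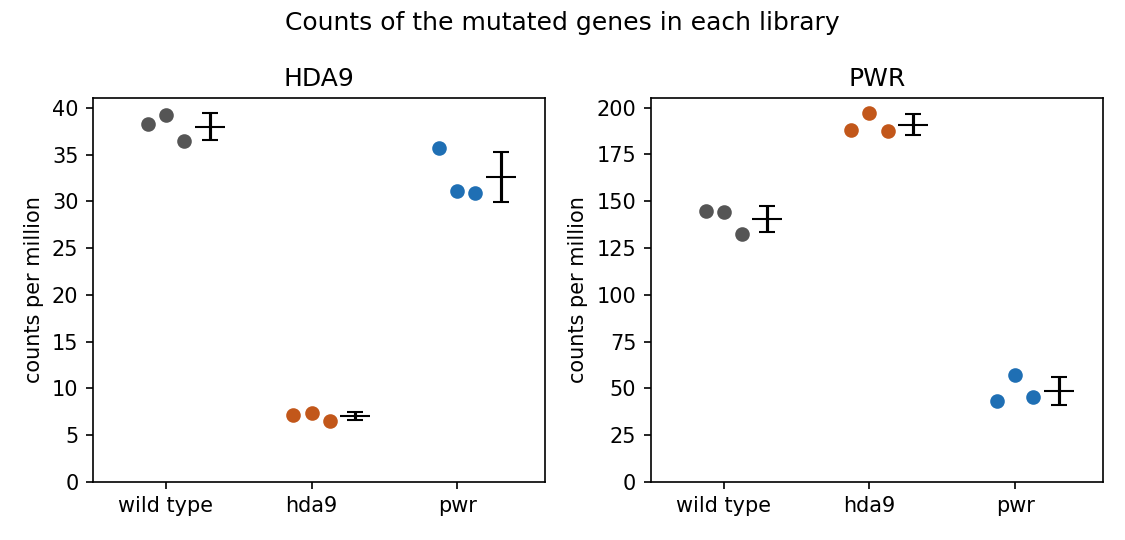
CPM (y axis) of HDA9 and PWR in each library (points) of wild type, hda9 and pwr (x axis), with the mean and SD of the 3 libraries of a group as a black bar. HDA9 lies at 7.04 CPM in hda9 against 38.0 CPM in WT, and PWR at 48.7 CPM in pwr against 140.7 CPM in WT.

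In hda9, DREB26, an AP2/ERF transcription factor, rose by a log2 fold change of 3.92 (SE 0.16, adjusted p = 4.3e-08, n = 3 per group), and the ethylene synthesis genes ACS11 and ACS8 by 3.89 (SE 0.24) and 2.88 (SE 0.34). XTR6 and XTH18, which encode xyloglucan-modifying enzymes, rose by 3.78 (SE 0.32) and 2.83 (SE 0.24), PHI-1 by 3.43 (SE 0.19), the auxin synthesis gene YUC5 by 2.92 (SE 0.32), the ABA catabolism gene CYP707A3 by 2.75 (SE 0.35) and the receptor kinase gene WAKL2 by 2.63 (SE 0.26). LRX2, a leucine-rich repeat extensin of the cell wall, had 4.71 (SE 0.41), but WT held only 1, 4 and 1 reads of it against 132 in all in hda9, so the size is uncertain (interval 3.61 to 6.24 for counting error only). The largest fall was that of MRD1 (AT1G53480), with a log2 fold change of -6.16 (SE 0.14, adjusted p = 2.9e-10), and the meiotic crossover gene HEI10 (AT1G53490), which overlaps it on the other strand, fell by 3.61 (SE 0.12). TPS04, which encodes a terpene synthase, had a log2 fold change of -4.64 (SE 0.69), the beta-amylase gene BAM5 -4.34 (SE 0.46), the phosphatase genes PAP14 and PS2 -3.70 (SE 0.94) and -3.52 (SE 0.45), and ALD1, needed for pipecolate synthesis, -3.67 (SE 0.85). MEE3, the acetyltransferase gene CHAT and the transcription factor gene ERF53 had log2 fold changes of -3.52 (SE 0.47), -3.51 (SE 0.35) and -3.07 (SE 0.41).

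In all, 6897 of 20171 genes differed between hda9 and WT, 3558 higher and 3339 lower. At an absolute log2 fold change of at least 1 there were 758, 286 higher and 472 lower. Of the calls, 51.6% were higher with TMM factors and 32.9% with upper-quartile factors, which shift the median log2 fold change of all genes to -0.08. With loess offsets 6238 genes were called, of which 4860 were among the 6897. The split at an absolute log2 fold change of at least 1 then turned from 37.7% to 62.9% higher. Leaving out WT replicate 1, 2 or 3 gave 5066, 4932 and 6198 calls, and leaving out hda9 replicate 1, 2 or 3 gave 7137, 5450 and 6085. PAP14 was not called by DESeq2 (adjusted p = 0.0569).

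**Figure D2:**
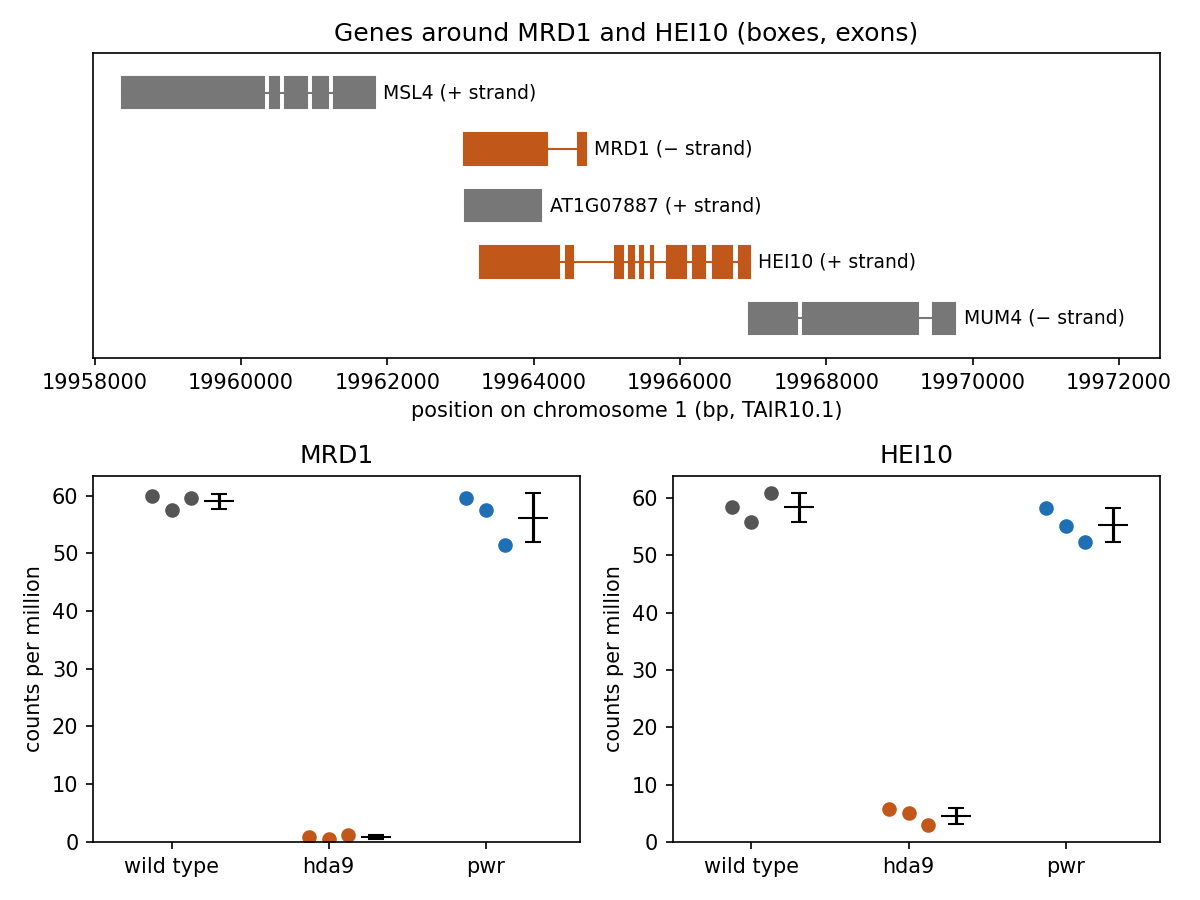
The upper panel maps MRD1, HEI10 and their neighbours on chromosome 1 (x axis, position in base pairs, boxes for exons), and the lower panels give the CPM (y axis) of MRD1 and HEI10 in each library (points) of the 3 genotypes (x axis), with mean and SD as a black bar. MRD1 lies at 0.847 CPM and HEI10 at 4.57 CPM in hda9, against 59.1 and 58.5 CPM in WT.

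Many of the same genes led the rises in pwr: 9 of the 10 largest named rises were common to both mutants. ACS11 rose by a log2 fold change of 3.82 (SE 0.24), DREB26 by 3.73 (SE 0.16, adjusted p = 2.2e-07), XTR6 by 3.44 (SE 0.32), CYP707A3 by 3.42 (SE 0.33) and PHI-1 by 3.31 (SE 0.19), each over 3 libraries per group. ACS8 rose by 3.29 (SE 0.33), YUC5 by 3.09 (SE 0.31), XTH18 by 2.79 (SE 0.24) and RAS1 by 2.76 (SE 0.25). LRX2 had 4.82 (SE 0.40), again against 1, 4 and 1 reads in WT (interval 3.76 to 6.38 for counting error only). The plant defensin genes PDF1.3, PDF1.2C and PDF1.2B had log2 fold changes of -5.78 (SE 1.29), -5.58 (SE 1.21) and -4.87 (SE 1.18), from WT levels that themselves varied widely, as for PDF1.3 at 11.3 ± 7.4 CPM. These defensin copies are near-identical, so reads can be split between them and each value is uncertain. TPS04 had -5.34 (SE 0.73), TAT3, a tyrosine aminotransferase gene induced by jasmonate, -4.41 (SE 0.97), CYP82G1, which acts after TPS04 in homoterpene synthesis, -4.27 (SE 0.70) and UGT76B1 -4.14 (SE 0.92). In pwr PDF1.3, PDF1.2C, PDF1.2B, CYP82G1 and UGT76B1 held 5, 9, 6, 7 and 8 reads over the 3 libraries, so the sizes of these falls are uncertain. Their intervals for counting error only were -7.47 to -4.60, -6.73 to -4.66, -6.38 to -3.77, -5.63 to -3.22 and -5.37 to -3.12. BAM5 had -3.78 (SE 0.43), the senescence-associated gene SAG13 -3.75 (SE 0.83) and MDHAR -3.90 (SE 1.12), the last with an adjusted p of 0.021 that became 0.0589 without WT replicate 1, 0.0718 without pwr replicate 1 and 0.0735 without pwr replicate 3.

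The comparison of pwr with WT called 6326 genes, 3232 higher and 3094 lower, of which 725 had an absolute log2 fold change of at least 1 (267 higher, 458 lower). The share of higher calls was 51.1% with TMM factors and 32.6% with upper-quartile factors, which shift the median of all genes to -0.08. At an absolute log2 fold change of at least 1 it was 36.8%, and 61.4% with loess offsets. With loess offsets 5400 genes were called, of which 4193 were among the 6326. The number of calls was 3917 without pwr replicate 2 and 4126 without WT replicate 1.

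Most measured genes of flavonoid and anthocyanin synthesis were called lower in each mutant. In hda9, all 16 measured members fell, 16 adjusted over the list alone, with a median log2 fold change of -1.10. DFR, an enzyme of anthocyanin synthesis, fell from 14.2 ± 0.88 to 2.19 ± 0.37 CPM (log2 fold change -2.67, SE 0.16, adjusted p = 1.1e-06), CHS, which starts the pathway, had -0.95 (SE 0.09), FLS1 -0.95 (SE 0.09) and the transport gene GSTF12 -1.68 (SE 0.16). In pwr, 11 of the 16 fell, 13 adjusted over the list alone, with a median of -0.69. DFR had -1.64 (SE 0.15), the regulator MYB111 -1.11 (SE 0.15), CHS -0.61 (SE 0.08) and FLS1 -0.59 (SE 0.08). No member rose in either mutant, and 14 fell in hda9 and 9 in pwr with loess offsets or with DESeq2. The list stood below other genes in hda9 (camera adjusted p = 1.4e-10, and adjusted p = 0.0351 with an estimated correlation) and in pwr (7.2e-07), where the call was lost at an adjusted p = 0.102 with an estimated correlation. Fry found the list lower in hda9 and in pwr (adjusted p = 1.1e-05 and 8.6e-05).

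**Figure D3:**
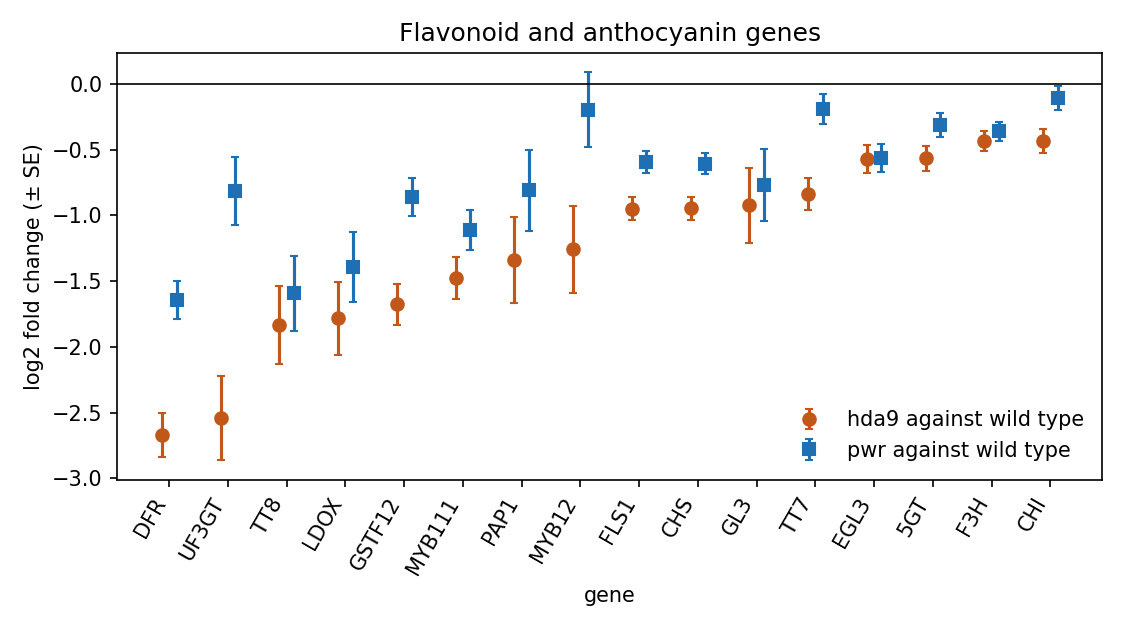
Log2 fold change (y axis) of each measured flavonoid and anthocyanin gene (x axis) in hda9 (circles) and pwr (squares) against wild type, with bars of 1 SE from 3 libraries per group. DFR lies lowest in both mutants, at -2.67 in hda9 and -1.64 in pwr.

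Genes of the ABA, drought and cold list moved both ways in hda9, where 7 of 27 rose and 8 fell, the same numbers adjusted over the list alone. CYP707A3 and CYP707A1, which encode ABA 8'-hydroxylases, rose by 2.75 (SE 0.35) and 1.15 (SE 0.13), and the dehydrin gene COR47 by 0.41 (SE 0.06). CBF3, a transcription factor of the cold response, fell by 2.53 (SE 0.21, adjusted p = 8.5e-06). The median was 0.05, the mean was -0.06, and camera pointed higher (adjusted p = 0.810). In pwr, 13 rose and 3 fell (14 and 3 adjusted over the list alone): CYP707A3 rose by 3.42 (SE 0.33), CYP707A1 by 0.98 (SE 0.13) and the dehydrin gene ERD10 by 0.41 (SE 0.06), while CBF3, CBF1 and RAB18 fell, with log2 fold changes of -1.14 (SE 0.18), -1.10 (SE 0.39) and -0.30 (SE 0.10). The list stood above other genes in pwr (camera adjusted p = 0.0105), a call lost with an adjusted p = 0.529 with an estimated correlation. Fry found the list higher in pwr (adjusted p = 0.0045) but not in hda9 (0.381). In pwr only 1 member was lower with DESeq2, with loess offsets (CBF1 at 0.169, RAB18 at 0.0672), and without WT replicate 2, WT replicate 3, pwr replicate 2, pwr replicate 3 or hda9 replicate 2.

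Auxin-related growth genes rose more often than they fell. Of 28 members, 9 were higher and 3 lower in hda9 (9 and 3 adjusted over the list alone), and 10 higher and 3 lower in pwr (11 and 3 adjusted over the list alone). The auxin response genes IAA6 and IAA19 rose by 2.37 (SE 0.20) and 0.81 (SE 0.09) in hda9, with XTH15, which shares 31.6% of its exon bases with another gene, by 1.27 (SE 0.11) and PIF5, a transcription factor of shade growth, by 0.48 (SE 0.06). In pwr, IAA6 rose by 1.91 (SE 0.21), GH3.5 by 0.76 (SE 0.11), IAA19 by 0.69 (SE 0.09) and PIF5 by 0.48 (SE 0.05). The 3 members that fell were YUC2, TAA1 and SAUR15, in hda9 with log2 fold changes of -1.27, -0.78 and -0.65 and in pwr of -0.91, -0.31 and -1.15. With loess offsets 2 were lower in each mutant, and the calls of SAUR15 in hda9 (0.0874) and TAA1 in pwr (0.105) were lost. Camera did not separate the list from other genes (adjusted p = 0.155 in hda9, 0.135 in pwr), while fry found a move towards higher values (0.0029 and 0.0043).

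NLR immune receptor genes also moved both ways. In hda9, 11 of 26 rose and 6 fell (13 and 8 adjusted over the list alone), and in pwr 11 rose and 7 fell (11 and 8 adjusted over the list alone). The helper receptor genes ADR1, ADR1-L1 and ADR1-L2 rose by 0.72 (SE 0.09), 0.51 (SE 0.07) and 1.03 (SE 0.12) in hda9, and ADR1 and ADR1-L1 by 0.85 (SE 0.08) and 0.60 (SE 0.07) in pwr. SOC3 had log2 fold changes of -1.65 (SE 0.16) in hda9 and -1.78 (SE 0.16) in pwr, where CHS1 had -1.84 (SE 0.20). CHS1 shares 90.5% of its exon bases with the SOC3 locus on the other strand, so these 2 values may not be separate. Camera gave adjusted p = 0.520 in hda9, where the median of 0.14 and the mean of -0.003 differ in sign, and 0.336 in pwr. With upper-quartile factors the split in hda9 was 7 higher and 9 lower, with loess offsets 7 and 7, and without hda9 replicate 2 there were 7 higher. In pwr loess offsets gave 9 and 6. Without pwr replicate 1, 4 were lower in pwr.

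Salicylic acid defence genes included several large falls. In hda9, 5 of 16 fell (6 adjusted over the list alone) and none rose: ALD1, NIMIN1, PBS3, PAD4 and ICS1, with log2 fold changes of -3.67 (SE 0.85), -1.68 (SE 0.27), -1.66 (SE 0.32), -0.72 (SE 0.08) and -0.38 (SE 0.12). With loess offsets ICS1 in hda9 was not called (0.0663), and 5 members were lower in pwr. In pwr, 7 fell and 2 rose (7 and 3 adjusted over the list alone). PR2, a pathogenesis-related glucanase gene, had a log2 fold change of -3.56 (SE 0.77), PBS3 -1.65 (SE 0.31), NIMIN1 -1.16 (SE 0.25) and PAD4 -0.42 (SE 0.08), while CBP60G and WRKY70 rose by 0.77 (SE 0.19) and 0.39 (SE 0.11). The salicylic acid list had camera adjusted p = 0.0904 in hda9 and 0.235 in pwr, and adjusted p = 0.829 and adjusted p = 0.751 with an estimated correlation. At the preset correlation, leaving out WT replicate 2 gave 0.0018 and 0.0102, and leaving out hda9 replicate 3 gave 0.0089 with 10 of 17 lower in hda9, while the correlation estimated over all libraries was 0.523 in hda9 and 0.514 in pwr. In hda9, 2 members were higher with the replicate number as a block and without WT replicate 3, and 1 without hda9 replicate 1. In pwr, 4 were higher without hda9 replicate 1, and 1 without WT replicate 1, WT replicate 2, pwr replicate 2 or pwr replicate 3.

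Among jasmonate and wounding genes, 4 of 18 rose and 3 fell in hda9 (4 and 3 adjusted over the list alone). JAZ7, a repressor of jasmonate responses, rose by 2.22 (SE 0.41) and AOS, an enzyme of jasmonate synthesis, by 0.37 (SE 0.09), with JAZ1 at 0.52 and VSP2 at 0.33. JAZ10 had -0.67 (SE 0.17, not called with loess offsets at 0.0664), OPR3 -0.38 (SE 0.08) and PDF1.3 -2.63 (SE 0.90). With loess offsets the calls of PDF1.3 (0.0943) and VSP2 (0.0780) were also lost and MYC2 was lower (-0.28, 0.0484), with 3 higher and 2 lower. In pwr, 5 rose and 6 fell (6 and 6 adjusted over the list alone). JAZ1 rose by 0.76 (SE 0.15) and AOS by 0.44 (SE 0.09), with JAZ7 at 1.71, VSP2 at 0.41 and MYC2 at 0.34, while PDF1.2C had -5.58 (SE 1.21) and JAZ10 -0.81 (SE 0.17). The falls in pwr include PDF1.3, PDF1.2C and PDF1.2B, near-identical copies with few reads in pwr, so they may not be separate. With loess offsets MYC2 in pwr was not called (0.0780). The jasmonate list had camera adjusted p = 0.810 in hda9 and 0.552 in pwr, where the median of 0.11 and the mean of -0.90 differ in sign. In hda9 the falls numbered 5 with the replicate block, 7 without hda9 replicate 3 and 5, beside 2 rises, without WT replicate 2.

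Of 21 leaf senescence genes, 6 rose and 5 fell in hda9 (6 and 7 adjusted over the list alone). SEN4 rose by 1.08 (SE 0.13), SAG20 by 0.92 (SE 0.13) and SEN1 by 0.68 (SE 0.15), and NPX1 fell by 0.38 (SE 0.08), with SAG13, NAC092, NYE1 and NYC1 at -2.32, -0.83, -0.23 and -0.23. With loess offsets 3 fell in hda9, as with DESeq2, and SAG13 (0.0662) and NYE1 (0.0778) were not called. In pwr, 9 rose and 2 fell (9 and 3 adjusted over the list alone): SEN4, SAG20 and the transcription factor gene ORS1 rose by 0.91 (SE 0.13), 0.72 (SE 0.13) and 0.55 (SE 0.12), and NPX1 and SAG13 fell, with -0.36 (SE 0.08) and -3.75 (SE 0.83). Camera did not separate the list in hda9 (adjusted p = 0.866) or pwr (0.145). The falls in hda9 numbered 3 without WT replicate 1 or hda9 replicate 1 and 7 with upper-quartile factors, and the rises in pwr numbered 4 without pwr replicate 2. The falls in pwr numbered 3 with loess offsets and 4 with upper-quartile factors.

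Flowering time genes rose slightly more often than they fell. In hda9, 7 of 25 rose and 2 fell, and in pwr 5 rose and 1 fell, the same numbers adjusted over the list alone. With loess offsets these were 9 and 3 in hda9 and 7 and 1 in pwr. TEM1, a repressor of FT, rose by 0.46 (SE 0.08) in hda9 and 0.65 (SE 0.08) in pwr, and TEM2 by 0.73 (SE 0.12) in pwr. SPL4 rose in hda9 by 0.48 (SE 0.09) and GI in pwr by 0.37 (SE 0.08). SNZ had -0.40 (SE 0.07) in hda9 and -0.32 (SE 0.07) in pwr, and SMZ, which shares 30.6% of its exon bases with another gene, -0.63 (SE 0.15) in hda9. FT, the mobile flowering signal, had a log2 fold change of 0.22 (SE 0.11, adjusted p = 0.137, and 0.0262 with loess offsets) in hda9 and rose by 0.45 (SE 0.10, adjusted p = 0.0077) in pwr. AGL19 rose by 0.96 (SE 0.29, adjusted p = 0.024) and 0.87 (SE 0.29, adjusted p = 0.039), at 1.54 ± 0.35 CPM in WT. In hda9 its call ended with DESeq2 (0.0653) and without WT replicate 1 (0.103), hda9 replicate 1 (0.0504) or hda9 replicate 2 (0.104), and in pwr with DESeq2 (0.104), with upper-quartile factors (0.0564) and without any 1 of the 6 libraries compared (0.0587 to 0.151).

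SOC1 rose by 0.36 (SE 0.09, adjusted p = 0.0088; 0.0757 with loess offsets) in hda9 and had a log2 fold change of 0.14 (SE 0.09, adjusted p = 0.249) in pwr. FLC, a repressor of flowering, had -0.11 (SE 0.20, adjusted p = 0.701) in hda9 and -0.34 (SE 0.20, adjusted p = 0.217) in pwr, where leaving out pwr replicate 2 gave -0.64 at 0.0345. FLC shares 68.1% of its exon bases with an antisense gene that the table does not count. Camera did not separate the flowering list from other genes in hda9 (adjusted p = 0.309) or pwr (0.589). There were 4 rises in hda9 without WT replicate 1, and in pwr 3 falls without hda9 replicate 1 and 2 without pwr replicate 2.

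Among 8 measured floral organ identity genes, SEP3 and SHP1 rose in both mutants, also adjusted over the list alone (2 in each), and none fell, while with upper-quartile factors 1 fell in hda9 and with loess offsets 3 rose there. SEP3 rose by 0.45 (SE 0.10) in hda9 and 0.72 (SE 0.10) in pwr, and SHP1 by 0.61 (SE 0.14) and 0.45 (SE 0.14). The SHP1 call in pwr (adjusted p = 0.032) ended without WT replicate 1 (0.0632), WT replicate 3 (0.0948), pwr replicate 2 (0.117) or pwr replicate 3 (0.0751), with DESeq2 (0.0762) and with upper-quartile factors (0.0778). Of 5 shoot meristem genes measured, STM, a homeobox gene of the meristem, rose by 0.55 (SE 0.09) in hda9 and 0.68 (SE 0.08) in pwr, also adjusted over the list alone (1 in each). Camera gave adjusted p = 0.547 and 0.376 for the floral list and 0.866 and 0.552 for the meristem list, whose median in hda9 was 0.04 and mean -0.09. Fry found the meristem list higher in pwr (0.0011), and without hda9 replicate 1 there was 1 meristem gene lower in hda9.

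In hda9, 6 of 17 clock genes rose and 2 fell (6 and 4 adjusted over the list alone), and in pwr 6 rose and none fell (6 and 0 adjusted over the list alone), while with loess offsets 5 rose and PRR5 fell (-0.19, 0.0127) and with the replicate block 1 fell. BOA rose by 0.60 (SE 0.05) in hda9 and 0.50 (SE 0.05) in pwr, LUX by 0.44 (SE 0.05) and 0.37 (SE 0.05), and ZTL by 0.28 (SE 0.05) and 0.32 (SE 0.05). RVE1 rose in pwr by 0.54 (SE 0.11), and in hda9 PRR9 and PRR5 had -1.20 (SE 0.23) and -0.19 (SE 0.06). Camera gave adjusted p = 0.214 in hda9, where the median was 0.13 and the mean -0.02, and 0.106 in pwr, while fry found higher values in both (0.0052 and 0.0028). In hda9, 4 genes were lower with the replicate block and without hda9 replicate 1, and 1 without WT replicate 2 or hda9 replicate 2, and in pwr camera gave 0.0359 without WT replicate 1, where all libraries gave adjusted p = 0.456 with an estimated correlation. BOA shares 45.9% and LUX 17.8% of their exon bases with another gene.

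Of 18 glucosinolate genes, 3 rose and 5 fell in hda9 (4 and 5 adjusted over the list alone), and 3 rose and 2 fell in pwr (3 and 2 adjusted over the list alone). MYB51, a regulator of indole glucosinolates, rose by 0.92 (SE 0.11) and 1.06 (SE 0.11), CYP79B3, an enzyme of the same branch, by 0.51 (SE 0.07) and 0.60 (SE 0.07), and CYP79B2 by 0.32 and 0.40. MYB76, a regulator of the aliphatic branch, had -0.77 (SE 0.14) and -0.72 (SE 0.14), MYB34 -0.29 (SE 0.06) and -0.27 (SE 0.06), and in hda9 FMO-GSOX1 had -0.35 (SE 0.06), with MAM3 at -0.32 and BAT5 at -0.17. The glucosinolate list had camera adjusted p = 0.810 and 0.552. With loess offsets CYP79B2 (0.115) and MAM3 (0.0918) were not called in hda9. The falls in hda9 numbered 9 with loess offsets and 3 without WT replicate 1 or 2 or pwr replicate 2. In pwr the falls numbered 4 without WT replicate 3, 4 with loess offsets and 5 with upper-quartile factors, and the rises 5 without hda9 replicate 3.

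Photosynthesis genes encoded in the nucleus had small rises with TMM factors, and more falls than rises with loess offsets. In hda9, 4 of 25 rose and none fell (3 and 0 adjusted over the list alone): LHCB1.4, LHCB6, PSAD2 and RBCS3B, by 0.52 (SE 0.08), 0.27 (SE 0.08), 0.22 (SE 0.06) and 0.18 (SE 0.06). In pwr, 6 rose and none fell (6 and 0 adjusted over the list alone), with LHCB1.4 at 0.40 (SE 0.08), PSAD2 at 0.21 (SE 0.06), RBCS3B at 0.19 (SE 0.06) and LHCB2.1 at 0.19 (SE 0.06). The list stood above other genes (camera adjusted p = 0.0026 and 0.0024), calls lost at adjusted p = 0.829 and adjusted p = 0.751 with an estimated correlation. Fry did not call the list in hda9 or pwr (adjusted p = 0.105 and 0.121). With loess offsets 1 gene was higher and 5 were lower in each mutant, and RBCS3B had log2 fold changes of -0.02 and -0.01. The number of rises in hda9 ranged from 2 without WT replicate 1 or 2 to 13 without hda9 replicate 1, and in pwr from 1 without WT replicate 2, pwr replicate 1 or pwr replicate 2, through 2 and 3 without WT replicates 1 and 3, to 15 without hda9 replicate 3.

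The single calls of the photosynthesis list were close to the threshold. In hda9, RBCS3B (adjusted p = 0.045) was at 0.0637 with the replicate block, at 0.0601, 0.115 and 0.106 without WT replicates 1, 2 and 3 and at 0.0661 without hda9 replicate 2, LHCB6 (0.018) was at 0.0566 without WT replicate 2, and PSAD2 (0.022) at 0.0502 without WT replicate 1. In pwr, the calls of PSAD2, RBCS3B and LHCB2.1 ended without WT replicate 2, WT replicate 3, pwr replicate 1 or pwr replicate 2, in this order at 0.0559, 0.0513, 0.0746 and 0.0846 for PSAD2, at 0.0832, 0.0711, 0.113 and 0.0947 for RBCS3B and at 0.0527, 0.0752, 0.0972 and 0.114 for LHCB2.1. Leaving out WT replicate 1 also ended the calls of PSAD2 (0.0611) and LHCB2.1 (0.0670). With the 6 compared libraries alone LHCB6 (0.0624), PSAD2 (0.0599) and RBCS3B (0.108) were not called in hda9. With upper-quartile factors RBCS3B was not called in hda9 (0.158), nor PSAD2 (0.0524), RBCS3B (0.0835) and LHCB2.1 (0.0832) in pwr. The replicate block ended the calls of RBCS3B (0.0503) and LHCB2.1 (0.0537) in pwr, and with loess offsets LHCB6 (0.392), PSAD2 (0.359) and RBCS3B (0.857) in hda9 and PSAD2 (0.576), RBCS3B (0.870) and LHCB2.1 (0.918) in pwr were not called. RBCS and LHCB genes have near-identical copies, so reads can be split between them.

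Among 13 reference genes commonly used for normalisation, 5 rose in hda9 (6 adjusted over the list alone) and 2 in pwr (2 adjusted over the list alone), and none fell. In hda9 these were YLS8 at 0.27 (SE 0.07), ACT8 at 0.24 (SE 0.08), ACT2 at 0.23 (SE 0.07), UBC9 at 0.22 (SE 0.05) and UBC21 at 0.21 (SE 0.07), and in pwr YLS8 at 0.25 (SE 0.06) and PP2AA3 at 0.19 (SE 0.06). With loess offsets 3 were higher and 3 lower in hda9, and 1 higher and 2 lower in pwr, and ACT8 (0.229) and ACT2 (0.198) in hda9 and PP2AA3 (0.194) in pwr were not called. With upper-quartile factors 2 were higher in hda9, and 1 higher and 1 lower in pwr. Without WT replicate 1, WT replicate 2 or hda9 replicate 2, the rises in hda9 numbered 3, 2 and 3, and in pwr they numbered 5 without hda9 replicate 3. ACT2 lost its call in each of these 3 hda9 cases (0.0706, 0.0973 and 0.0502), UBC21 without WT replicate 2 (0.110), WT replicate 3 (0.0883), hda9 replicate 1 (0.0778) or hda9 replicate 2 (0.0640), and PP2AA3 without WT replicate 1 (0.0847) or pwr replicate 1 (0.0875). Upper-quartile factors ended the calls of ACT2 (0.0541), UBC21 (0.164) and PP2AA3 (0.0753), the fit of the 6 compared libraries alone that of ACT2 (0.0641), and DESeq2 that of UBC21 (0.115). The reference list had camera adjusted p = 0.120 in hda9 and 0.247 in pwr.

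Heat shock genes were measured for 6 members. In hda9, HSP18.2, HSP101 and HSP90.1 fell, with -0.95 (SE 0.19), -0.46 (SE 0.13) and -0.45 (SE 0.14), 3 of 6 and 3 adjusted over the list alone, and none rose. In pwr, HSP18.2 had -0.85 (SE 0.19) and HSP70 rose by 0.79 (SE 0.18), 1 each and 1 each adjusted over the list alone. Camera gave adjusted p = 0.120 and 0.552. The HSP101 call ended without WT replicate 1 (0.0617) or WT replicate 2 (0.0612), and that of HSP90.1 without WT replicate 2 (0.0571), WT replicate 3 (0.0620), hda9 replicate 1 (0.0865) or hda9 replicate 2 (0.0506) and with loess offsets (0.0888). With loess offsets 2 of the 6 were lower in hda9.

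Other histone deacetylase genes changed little. Of 15 measured, SRT2 and HDT4 fell in hda9, with -0.30 (SE 0.07) and -0.23 (SE 0.06), and SRT1, HDT4 and SRT2 in pwr, with -0.45 (SE 0.11), -0.34 (SE 0.06) and -0.23 (SE 0.07), also adjusted over the list alone (2 and 3), and none rose. With loess offsets HDA18 rose by 0.57 (0.0343) in hda9 and 0.64 (0.0226) in pwr, and HDA19 had -0.15 (0.0107) and -0.14 (0.0220). Camera gave adjusted p = 0.821 and 0.552. HDT4 in hda9 was not called with DESeq2 (0.106), with loess offsets (0.0533) or without hda9 replicate 2 (0.0505). In pwr, SRT2 was not called with DESeq2 (0.120), with loess offsets (0.0856) or without WT replicate 1 (0.104), WT replicate 2 (0.0826), pwr replicate 2 (0.118) or pwr replicate 3 (0.0529). With upper-quartile factors 4 were lower in hda9.

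Of 21 root tissue markers, 10 were measured. The nitrate transporter gene NRT2.1, with 8 reads in all in hda9, had -2.23 (SE 0.57, interval -3.56 to -1.18 for counting error only) and the iron reductase gene FRO2 -0.74 (SE 0.26) in hda9, 2 genes, and 1 adjusted over the list alone. In pwr, PHO1 rose by 0.18 (SE 0.06), 1 gene, and 0 adjusted over the list alone. For the root list camera adjusted p was 0.536 and 0.733. FRO2 (adjusted p = 0.045) was at 0.0666 with the replicate block, at 0.191, 0.0744, 0.141 and 0.102 without WT replicate 2, WT replicate 3, hda9 replicate 2 and hda9 replicate 3, at 0.138 with DESeq2, at 0.0556 without a filter, at 0.0707 with the 6 compared libraries alone and at 0.206 with loess offsets. PHO1 (0.030) was not called without WT replicate 1 (0.10003), WT replicate 3 (0.0773), pwr replicate 1 (0.0642), pwr replicate 2 (0.0981) or pwr replicate 3 (0.0537), nor with DESeq2 (0.0814), upper-quartile factors (0.151) or loess offsets (0.126). In hda9 1 gene was lower without any 1 of the pwr replicates, and in pwr 2 were lower without hda9 replicate 1, and 1 without WT replicate 3, hda9 replicate 2 or hda9 replicate 3. Of 34 seed maturation genes 7 were measured, and 0 were called in either mutant by edgeR, over all genes or adjusted over the list alone, or by DESeq2 (camera adjusted p = 0.810 and 0.391). Without hda9 replicate 3, 9 were measured, with 1 higher in hda9 and 1 lower in pwr.

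Calls were largely shared between the mutants. Of the genes called in both, 2509 were higher in each and 2125 lower in each, 4634 in all, and 7 moved in opposite directions. That is 67.2% of the hda9 calls and 73.3% of the pwr calls, where independent lists would share 570 higher and 512 lower. Both mutants have the trend of direction with expression level described below, for which independent lists make no allowance. With loess offsets, which remove such trends, 2219 higher and 1715 lower calls were shared, where independent lists would share 473 and 365. Across all tested genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.837 (jackknife error 0.0594 over the libraries) and Spearman's rho of 0.838. With loess offsets Pearson's r was 0.814. Both comparisons use the same WT libraries. In 20 simulations of unchanged groups, with simulated WT libraries shared in the same way, r averaged 0.476 with 0 shared calls. The simulated libraries were independent, without the deviations shared by WT and hda9 libraries of the same number. The covariance was 0.190 against 0.0150 in the simulations, a difference of 0.175. With 3 WT libraries, the controls cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

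**Figure D4:**
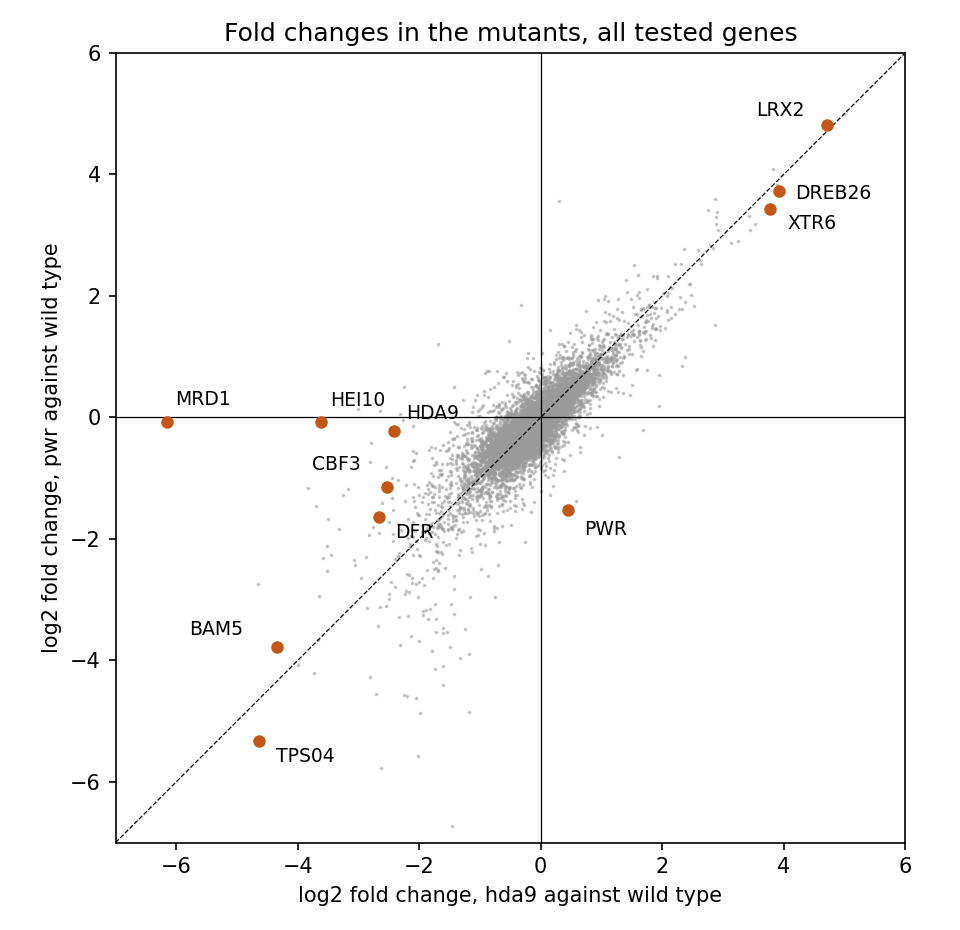
Log2 fold change against wild type of each tested gene (grey points) in hda9 (x axis) and pwr (y axis), with 11 named genes marked and the line of equal change dashed. DREB26 lies at 3.92 and 3.73, close to that line, and MRD1 at -6.16 and -0.07, far from it.

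Directly compared, pwr and hda9 differed in few genes. HDA9 was higher in pwr by a log2 fold change of 2.197 (SE 0.09) and PWR lower, at -1.97 (SE 0.09). MRD1 was higher in pwr by 6.09 (SE 0.14, adjusted p = 4.0e-10) and HEI10 by 3.53 (SE 0.12, adjusted p = 2.4e-08), at 56.3 ± 4.2 and 55.3 ± 2.9 CPM in pwr (n = 3). NAS3, a nicotianamine synthase gene, and PUB19, a ubiquitin ligase gene, were higher by 1.97 (SE 0.36) and 1.62 (SE 0.27). The iron response genes bHLH38 and BHLH100 were lower, with -1.49 (SE 0.20) and -1.25 (SE 0.19), as were ARR6, a cytokinin response gene, with -0.998 (SE 0.19) and XTH15 with -0.84 (SE 0.11). In all, 85 genes were called, 63 higher and 22 lower in pwr, and 19 of them had an absolute log2 fold change of at least 1. Single libraries decided much of this count: it was 10, 11 and 49 without hda9 replicates 1, 2 and 3, 9, 11 and 252 without pwr replicates 1, 2 and 3, and 27 and 148 without WT replicates 2 and 3.

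The last 6 of these genes depended on single libraries. Adjusted p for NAS3 was 0.135, 0.142, 0.198 and 0.175 without hda9 replicate 1, hda9 replicate 2, pwr replicate 1 and pwr replicate 2, and bHLH38 had 0.0751, 0.0827 and 0.105 without the first 3 of these libraries. Without hda9 replicates 1, 2 and 3 and pwr replicates 1 and 2, PUB19 had 0.0908, 0.130, 0.0760, 0.166 and 0.160, BHLH100 had 0.0751, 0.0827, 0.0533, 0.164 and 0.154, and ARR6 had 0.132, 0.142, 0.103, 0.170 and 0.162. XTH15 lost its call without hda9 replicate 2 (0.0827) and pwr replicate 1 (0.101). ARR6 was also not called with the replicate block (0.0687), with upper-quartile factors (0.0605) or at a filter of 1 CPM in 3 libraries (0.0509), and with loess offsets and the block NAS3 (0.0658), PUB19 (0.0561) and ARR6 (0.0657) were not called. HDA9, PWR, MRD1 and HEI10 kept theirs without any 1 library.

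Few list members differed between pwr and hda9. Of the ABA list, only CBF3 was called higher in pwr (1.39, SE 0.23, adjusted p = 0.034) and 12 of 27 were higher adjusted over the list alone. Of the flavonoid list, only DFR was called higher (1.03, SE 0.19, adjusted p = 0.043) and 9 of 16 were higher adjusted over the list alone. Camera called both lists (adjusted p = 6.6e-08 and 3.9e-08). Neither camera call held with an estimated correlation (adjusted p = 0.130 and adjusted p = 0.0517), while fry placed both lists higher in pwr (adjusted p = 0.0230 and 0.0042). Camera also placed the senescence, glucosinolate and heat shock lists higher in pwr (0.0043, 0.0139 and 0.0197), with no member called and 4, 1 and 2 adjusted over the list alone, and with adjusted p = 0.319, adjusted p = 0.497 and adjusted p = 0.319 with an estimated correlation. Fry did not call these lists (adjusted p = 0.230, 0.293 and 0.230). In the other lists the only called members were XTH15, HDA9 and PWR, and no camera call was made, while fry placed the meristem list higher in pwr (adjusted p = 0.0268).

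These few list calls in pwr against hda9 also moved with single libraries. The ABA list had 4 genes higher without WT replicate 3, 3 without pwr replicate 3, and 0 without WT replicate 2, any hda9 replicate, pwr replicate 1 or pwr replicate 2. The flavonoid list had 2 without pwr replicate 3, and 0 without WT replicate 1, WT replicate 2, any hda9 replicate, pwr replicate 1 or pwr replicate 2. The NLR, jasmonate and salicylic acid lists each had 1 gene higher without WT replicate 3, the senescence list 1 without WT replicate 1, and the auxin, jasmonate, senescence and heat shock lists 1 each without pwr replicate 3, when 1 deacetylase gene was lower.

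The direction of change followed expression level. In the fifth of genes with the lowest mean expression, 22.1% of the calls in hda9 were higher, against 57.3% in the other classes (Fisher's exact test, p = 7.7e-108), and in pwr 24.1% against 56.9% (p = 3.8e-91). In the fifth with the highest expression, 90.8% and 95.3% were higher. Genes are not independent replicates, so these p-values overstate the evidence. With loess offsets, which remove such trends, the lowest class had 53.5% in both mutants, against 52.1% (Fisher's exact test, p = 0.449) and 54.3% (p = 0.690) in the other classes. By library, the log2 level of the lowest class relative to the highest was 0.05, 0.04 and -0.06 in WT, -0.16, -0.37 and -0.61 in hda9, and -0.40, -0.33 and -0.37 in pwr.

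**Figure D5:**
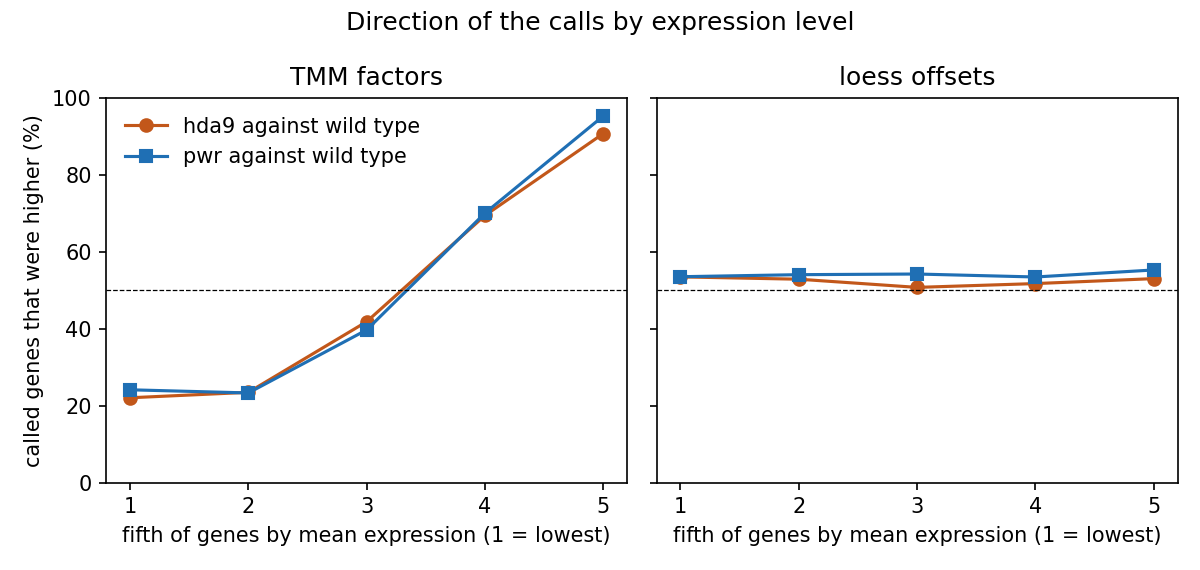
Share of called genes that were higher in the mutant (y axis, percent) in 5 classes of genes from lowest to highest mean expression (x axis), for hda9 (circles) and pwr (squares) against wild type, with TMM factors (left) and with loess offsets (right). With TMM factors the share runs from 22.1% to 90.8% in hda9 and from 24.1% to 95.3% in pwr, and with loess offsets it lies at 53.5% in the lowest class of both.

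The share of called genes near each mutated locus was compared with the rest of the genome. Within 1000 kb of HDA9, 55 of 179 genes were called in hda9, 30.7% against 34.2% elsewhere (odds ratio 0.853, Fisher's exact test, p = 0.343). Within 1000 kb of PWR, 146 of 458 were called in pwr, 31.9% against 31.4% (odds ratio 1.02, Fisher's exact test, p = 0.799).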

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

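In pwr compared directly with hda9, which tests the difference between the 2 mutant effects, 10 genes named by the rule set before the data were examined stood out. The tests of explanations for the MRD1 and HEI10 locus were chosen only after the result was seen. The 2 mutated genes are among the 10: HDA9 was higher in pwr (log2 fold change 2.197, SE 0.09, n = 3 libraries per group) and PWR lower (-1.97, SE 0.09).

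MRD1 and HEI10 differed most between the mutants, with log2 fold changes of 6.09 (SE 0.14) and 3.53 (SE 0.12) in pwr against hda9. MRD1 had 8, 5 and 7 counts in the hda9 libraries, against 634, 665 and 505 in WT and 485, 535 and 453 in pwr, and HEI10 had 54, 46 and 18 in hda9, 617, 647 and 517 in WT and 474, 513 and 461 in pwr. Against WT, MRD1 had -0.07 in pwr (adjusted p = 0.425) and HEI10 had -0.08 (0.468).

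The tables argue against a deletion that removes the genes on either side, since MSL4 and MUM4 had log2 fold changes of -0.52 (SE 0.14, adjusted p = 0.015) and -0.18 (SE 0.06, 0.042) in hda9, small beside -6.16 for MRD1. The similar levels of MRD1 and HEI10 may come from reads counted for both genes, which share 922 exonic bases on opposite strands. Their counts differed by at most 4.11% in any of the 6 WT and pwr libraries. Gene pairs with at least 200 counts together were compared, taking overlaps of at least 50% of the shorter gene's exon bases. With such overlaps on opposite strands 78 of 499 (15.6%) had counts within 10% of each other, against 240 of 7487 (3.21%) adjacent pairs without overlap (Fisher's exact test, p = 2.6e-27). Pairs with such overlaps on the same strand showed little excess, with 3 of 67 (4.48%) against 346 of 9928 (3.49%) adjacent pairs. Reads counted for both genes whatever their strand would raise this share too, which was not clearly seen in these 67 pairs. In hda9 the 2 counts were not alike, at 8, 5 and 7 for MRD1 and 54, 46 and 18 for HEI10. The value for HEI10 may still reflect MRD1 in part. A sequence change at the locus in the hda9 line, and a loss of transcription through HDA9, stay open, since the fall of MRD1 by -6.16 fits either and the table holds no sequence.

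The other 6 genes differed with less certainty. NAS3 was higher in pwr (1.97, SE 0.36, adjusted p = 0.043), with log2 fold changes against WT of -2.11 in hda9 and -0.14 in pwr, and PUB19 was higher (1.62, SE 0.27, 0.034), with -0.86 and 0.77. Lower in pwr were bHLH38 (-1.49, SE 0.20, 0.015), with 2.33 and 0.84 against WT, BHLH100 (-1.25, SE 0.19, 0.023), with 1.95 and 0.70, ARR6 (-0.998, SE 0.19, 0.0499), with 0.71 and -0.29, and XTH15 (-0.84, SE 0.11, 0.015), with 1.27 and 0.42. Without pwr replicate 1, none of the 6 was called, at adjusted p of 0.198, 0.166, 0.105, 0.164, 0.170 and 0.101 in the order given. Without hda9 replicate 2 none was called either, at 0.142, 0.130, 0.0827, 0.0827, 0.142 and 0.0827. Leaving out hda9 replicate 1 also ended the calls of NAS3 (0.135), PUB19 (0.0908), bHLH38 (0.0751), BHLH100 (0.0751) and ARR6 (0.132), leaving out pwr replicate 2 those of NAS3 (0.175), PUB19 (0.160), BHLH100 (0.154) and ARR6 (0.162), and leaving out hda9 replicate 3 those of PUB19 (0.0760), BHLH100 (0.0533) and ARR6 (0.103). ARR6 was also not called with the replicate block (0.0687), with upper-quartile factors (0.0605) or at a filter of 1 CPM in 3 libraries (0.0509), and with loess offsets and the block NAS3 (0.0658), PUB19 (0.0561) and ARR6 (0.0657) were not called. No cause for these 6 differences was tested. Of the exon bases of bHLH38, XTH15 and ARR6, 35.7%, 31.6% and 23.9% are shared with another gene.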

How the results depend on the processing

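All alternatives chosen before the data were examined were run, and the loess offsets were added after the data were seen. At an adjusted p under 0.01 the calls were 3815 in hda9, 3093 in pwr, 8 in pwr against hda9 and 2294 shared, and at an absolute log2 fold change of at least 1 they were 758, 725, 19 and 463. For pwr against hda9, DESeq2 called 184 genes, the fit without a filter 179, and loess offsets 158, or 152 with the replicate block. Leaving out 1 of the 6 compared libraries in turn gave 3917 to 5797 calls in pwr and 9 to 252 in pwr against hda9. Leaving out hda9 replicate 1, 2 or 3, which share the variance estimate, gave 7080, 6030 and 7581 calls in pwr. Without a filter the correlation of the fold changes was 0.672; the cause was not tested.

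Loess offsets ended the tilt of direction with expression level: the share of higher calls in the lowest class became 53.5% in hda9 and 53.5% in pwr, and 53.2% and 54.4% with the block. The photosynthesis list turned lower, at adjusted p = 0.255 and 0.273 with the block in hda9, and 0.0998 and 0.0984 in pwr. RBCS3B turned to -0.016 in hda9 and -0.0146 in pwr, and to -0.0171 and -0.0123 with the block. In hda9, 2 lists were called by camera, 1 with an estimated correlation, 1 with loess values and 1 with loess values and the block. In pwr, 3 were called, 0 with an estimated correlation, 5 by fry and 1 with loess values and the block, where the ABA list was at 0.0599. For single named genes, 2565 alternatives over 171 pairs of gene and comparison gave 2399 unchanged calls, 159 lost with the same sign and 3 gained. In the other 4, all of RBCS3B with loess offsets, the call was lost at values near 0 of changed sign (adjusted p = 0.857 and 0.870, and 0.761 and 0.833 with the block). Named genes were mostly chosen for large changes or small adjusted p, so these counts need not hold for other called genes. Over all genes, 4860 of the 6897 calls in hda9 and 4193 of the 6326 in pwr remained with loess offsets. Loess offsets with the block, but not without it, ended the calls of SRT1 (0.0558) and LHCB1.4 (0.0533) in pwr.

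With the replicate number as a block the calls were 6901 in hda9, 6251 in pwr and 113 in pwr against hda9. Only WT and hda9 showed deviations shared by number. Same-numbered libraries of WT and pwr had deviations correlated at -0.12, -0.01 and -0.13, and those of hda9 and pwr at -0.22, -0.19 and -0.24. Of 9 libraries, 6 correlated best with one of their own number. The block ended the calls of FRO2 (0.0666) and RBCS3B (0.0637) in hda9, RBCS3B (0.0503) and LHCB2.1 (0.0537) in pwr, and ARR6 (0.0687) in pwr against hda9, and changed no other call among the named genes.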

Other observations

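Some families of genes with the same annotated product, a grouping chosen after the data were seen, held more calls in one direction than other genes. Of xyloglucan endotransglucosylase genes, which remodel the cell wall, 13 of 19 were called higher in hda9 (68.4%, adjusted p = 1.8e-04, Fisher's exact test; 13 with loess offsets) and 12 of 19 in pwr (5.1e-04; 11 with loess offsets). Among them, XTH30 rose by a log2 fold change of 1.45 (SE 0.10) in hda9 and 1.18 (SE 0.10) in pwr, XTH25 by 2.29 (SE 0.36) and 1.99 (SE 0.37), and XTH17 by 0.96 (SE 0.07) and 1.02 (SE 0.07). Of arabinogalactan protein genes 15 and 13 of 24 were called higher (1.7e-04 and 0.0016; 17 and 13 with loess offsets), as were 8 of 14 phloem protein genes in each mutant (0.0282 and 0.0170; 9 and 9 with loess offsets).

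Genes of pentatricopeptide repeat proteins, many of which edit or process organelle RNA, held an excess of falls, although most were not called: 75 of 182 were lower in hda9 (41.2%, against 16.6% of all tested genes, adjusted p = 1.2e-12, Fisher's exact test; 51 with loess offsets) and 69 of 182 in pwr (37.9%, against 15.3%, 2.1e-11; 44 with loess offsets). The smaller family annotated PPR-like had 16 and 18 of 34 lower (0.0024 and 7.0e-05), which did not pass with loess offsets (9 and 8 lower, 0.430 and 0.405), and another annotated pentatricopeptide group 10 of 20 in hda9 (0.0179), which did not pass either (8 lower, 0.0887). The family of TPR-like proteins had 100 and 90 of 259 lower (1.2e-14 and 2.4e-12; 76 and 71 with loess offsets), pectin lyase-like proteins 19 and 17 of 45 (0.0025 and 0.0085; 20 and 15 with loess offsets), and cytochrome P450 genes 53 of 150 in hda9 (3.8e-06; 47 with loess offsets). Of 1084 tests over 271 families, 48 passed, and 25 of these also passed with loess offsets, while 15 others passed with loess offsets only. Among those, heat shock protein genes went from 8 to 17 of 24 lower in hda9 (0.336 to 4.2e-07) and from 4 to 14 of 24 in pwr (1 to 2.2e-05), so their result depends on the offsets. Members of a family are not independent, so these p-values overstate the evidence.

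Of the tests of explanations in the next paragraphs, only the list of touch and wound genes was written down before its result was seen; all others were chosen after the result was seen. Weakly expressed genes were lower in both mutants, with a log2 level of the lowest of 5 expression classes relative to the highest of -0.38 ± 0.22 in hda9 and -0.37 ± 0.034 in pwr (SD, n = 3), against 0.0098 ± 0.064 in WT. The tables argue against unequal numbers of counts alone, since after thinning to 1 library size the values were -0.37 ± 0.22 in hda9 and -0.36 ± 0.031 in pwr. Thinning of finished counts cannot show an effect that arose before counting. Within hda9 the trend was steepest in the smallest library, at -0.61 for 6450661 counts against -0.16 for 9417469. At near-equal totals of 8260650 and 8261697, WT replicate 3 had -0.06 and pwr replicate 1 had -0.40. The tables also argue against uniform background reads in WT, since the WT minus mutant difference at 4 to 8 CPM per kb was 2.88 times that at 1 to 2 in one mutant and 3.14 times in the other. Saturation or removal of duplicates at densely covered genes could not be decided: the log2 ratio to WT at 1 to 2 minus that at 4 to 8 CPM per kb was -0.155 ± 0.046 over the 6 mutant libraries, where a pure saturation effect would be flat, but the rise of 0.278 ± 0.14 at higher densities may still contain it, and the bounds of this test were rewritten after the densities were explored. A genotype effect stays open as a hypothesis, untested.

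The largest rises in both mutants included XTR6, XTH18, ACS8 and ACS11, which raises handling at harvest as a candidate explanation. A list of 20 rapid touch and wound genes, 19 measured, had a median log2 fold change of 0.58 in hda9 and 1.197 in pwr. Of these, 9 and 17 were higher (9 and 18 adjusted over the list alone, and 8 and 18 with loess offsets), and TCH4 rose by 1.98 (SE 0.15) and 1.80 (SE 0.15). WT libraries varied widely among themselves on several members, as on DIC2 (33.5 ± 25.0 CPM in WT, 65.1 ± 7.4 in hda9, 76.1 ± 2.6 in pwr) and SZF1 (78.0 ± 35.0, 180 ± 21 and 200 ± 2.6). TCH4 had a larger SD in hda9 (231 ± 34 CPM) than in WT (58.8 ± 15.2), at a higher mean. Relative to its mean, TCH4 varied more in WT. Both comparisons share these uneven WT libraries, so the sizes of the rises on such members are uncertain in both mutants. Camera called the list (adjusted p = 3.6e-04 and 4.4e-11), but not with an estimated correlation (adjusted p = 0.787 and 0.446). Fry called it in pwr (adjusted p = 0.0054) but not in hda9 (0.0669). Handling may account for part of the pattern, while the labels describe no harvest and an effect of genotype on these genes stays open, untested. The trend with expression level was small beside these rises: the class medians ran from -0.26 to 0.12 in hda9 and from -0.28 to 0.12 in pwr. With loess offsets the smallest of the 10 largest named rises of each mutant was still 2.79. The small size of the trend fixed that outcome in advance, so it is no separate evidence. In pwr against hda9, 0 of the list were called by edgeR and 9 adjusted over the list alone (camera adjusted p = 2.0e-08; adjusted p = 0.437 with an estimated correlation).

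The 6 libraries of a comparison can be split in 10 ways into 3 and 3, too few for a share under 0.05; these counts were made after the results were seen. In each comparison 1 split, the real one, gave as many calls by edgeR as were reported: 6897 in hda9, 6326 in pwr and 85 in pwr against hda9, where the highest of the other splits gave 0. Each other split puts both genotypes in each part, so a difference between genotypes widens the spread within the parts. Few calls in the other splits can follow from that alone, so they are no measure of chance. At an unadjusted p under 0.05 the real splits gave 9033, 8695 and 2724 genes and the highest other splits 2764, 1000 and 2832; the last places hda9 replicates 1 and 2 with pwr replicate 3. For hda9 against WT, whose numbers may pair the libraries, the other splits that part every such pair gave at most 143.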
